A study of Equus caballus with 14 samples.

How the data were processed

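Luteal biopsies of mares were sequenced as directional poly(A) libraries made from 1000 ng of total RNA, per the labels' protocols. The deposited table holds raw read counts per Ensembl gene for 14 libraries. Reads were trimmed with Trim Galore and aligned with STAR to EquCab3.0, per the submitters' processing notes. The versions, the counting tool and the annotation release are not given in the sources used here. Whether reads shared by near-identical genes were split or dropped is therefore unknown, and counts of such genes are uncertain.

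Each column was matched to its sample by the name that the label gives, and status and day were taken from the same labels. Replicate numbers follow the order of the samples and pair nothing. The mare and the corpus luteum come from the mare's name and the biopsy date in the titles. No 2 libraries were copies: the chi-square statistic per degree of freedom was at least 23.1 for every pair.

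Of 30371 genes, 7865 had no count in any library. Genes were kept by edgeR's filterByExpr over the 4 groups, which left 15437 genes with 99.974% of the counts. Counts were scaled by TMM, and CPM values are TMM-scaled. Log2 CPM used a prior count of 2. The main test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, in a model with 1 mean for each of the 4 groups over all 14 libraries, without a block. P-values were adjusted by the method of Benjamini and Hochberg within a comparison, with a threshold of 0.05. Because P13 holds 2 libraries, all groups share 1 estimate of the spread. Several libraries came from the same mare, so the libraries are not all independent. P-values without a block do not account for that.

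Pairing was checked with the correlation of deviations from group means. Mares are named in the labels, so libraries of the same mare are paired by design. Over 6 pairs from the same corpus luteum r ran from 0.03 to 0.52. Alternatives fixed before the data were examined were RLE size factors, other low-count filters, DESeq2 1.42.0, limma 3.58.1 with voom and the mare as a random block, the mare or the corpus luteum as a fixed block, biopsy month as a covariate, the compared libraries alone, the data without the corpus luteum that carries both status labels, and leaving out each library. Stability was measured as the SD of log2 CPM in genes with a mean of at least 10 CPM. Other splits of the libraries were tested with at most 100 regroupings.

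The scripts were tested on simulated counts. For pregnancy at day 11, 70% of genes changed 2-fold and 88% of genes changed 4-fold were recovered among 15217 genes. For pregnancy at day 13 the shares were 48% and 86% among 15193 genes. For the day effect they were 54% and 94% among 15221 genes in non-pregnant mares, and 50% and 90% among 15223 genes in pregnant mares. In each simulation 50 genes were changed at each of 2-, 4-, 8- and 16-fold, drawn from genes with a mean of at least 1 CPM. With fewer changed genes or less abundant ones the shares could be lower. The simulated libraries had no mare structure.

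The genes to be named were to be those with a symbol, the 10 highest and 10 lowest fold changes past the threshold or the 10 smallest p-values otherwise, plus a fixed set of steroidogenic and receptor genes. The reference table of assembly TB-T2T matched 0 of the Ensembl identifiers to a symbol. The rule could therefore not be applied. In its place, chosen after the files were seen, 1 gene higher and 1 gene lower with the smallest p and a mean of at least 1 CPM are given for each comparison of 2 groups. The tests of gene lists, the cell type markers and the ranks of candidate reference genes, all planned, were not run for the same reason. Coordinates are not given.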

Results

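The data are read counts per gene from 14 poly(A) RNA-seq libraries of equine corpus luteum, the progesterone-secreting gland that forms from the ovulated follicle. Tissue was taken by needle through the vaginal wall on day 11 or day 13 after ovulation. There were 4 non-pregnant libraries at day 11 (NP11), 4 non-pregnant at day 13 (NP13), 4 pregnant at day 11 (P11) and 2 pregnant at day 13 (P13). The submitters enrolled 8 mares, and the labels of these libraries name 6 mares and 8 corpora lutea. The mare Kate gave 4 libraries from 2 corpora lutea and the mare Emma gave 4 from 2. Kiwi and Cornelia gave 2 libraries each, and Roanie and Gisela 1 each at day 11. For 6 corpora lutea both days were sampled, so every day 13 library came from a gland already biopsied at day 11. Day and an earlier biopsy could therefore not be separated. The first corpus luteum of Kate is labelled pregnant at day 11 (P11 replicate 2) and non-pregnant at day 13 (NP13 replicate 1). Whether its status changed or a label is wrong is not known, and both libraries enter the group means as labelled.

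Total counts ran from 20182039 in NP13 replicate 2 to 32186736 in P13 replicate 1. The mean per group was 28702767 ± 3253072 counts (SD, n = 4) in NP11, 23582876 ± 2796267 counts (SD, n = 4) in NP13, 28612300 ± 2772275 counts (SD, n = 4) in P11 and 30551956 ± 2311929 counts (SD, n = 2) in P13. Of 30371 genes, 15437 had enough counts to be tested. The deposited table names genes by Ensembl identifier, and the reference table used here pairs none of these with a symbol, so the genes below are given by identifier.

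The first question was whether luteal expression at day 11 differed with pregnancy. No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. ENSECAG00000041112 had the smallest p among genes higher in pregnancy, at 21.2 ± 2.19 CPM (SD, n = 4) in P11 and 13.7 ± 2.11 CPM (SD, n = 4) in NP11. Its log2 fold change was 0.63 ± 0.14 (SE) with an adjusted p of 1 in edgeR. ENSECAG00000042557 had the smallest p among genes lower in pregnancy, at 2.43 ± 0.705 CPM (SD, n = 4) against 10.6 ± 5.21 CPM (SD, n = 4), a log2 fold change of -2.13 ± 0.41 (SE). At an unadjusted p under 0.05 there were 638 genes, 336 higher and 302 lower. Chance would give 772 if all libraries were independent, which they are not. With the mare as a fixed block in edgeR the count was 771. DESeq2 called 2 genes, both lower in pregnancy, among them ENSECAG00000042557 with an adjusted p of 0.00202. With the mare as a fixed block in edgeR, its log2 fold change was -1.48 with an adjusted p of 0.908, and over all alternatives its adjusted p ran from 0.00202 to 1. Among the 8526 genes with a mean of at least 10 CPM, the 95% confidence interval of the difference lay within 2-fold for 94.3% and within 1.5-fold for 79.8%.

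At day 13 the same comparison rested on 2 pregnant and 4 non-pregnant libraries, and edgeR again called 0 genes. ENSECAG00000011854 stood at 16.7 ± 2.21 CPM (SD, n = 2) in P13 and 7.30 ± 1.99 CPM (SD, n = 4) in NP13, a log2 fold change of 1.20 ± 0.28 (SE) with an adjusted p of 0.999 in edgeR. ENSECAG00000023115 stood at 6.42 ± 1.02 CPM (SD, n = 2) in P13 and 10.7 ± 1.33 CPM (SD, n = 4) in NP13, a log2 fold change of -0.73 ± 0.17 (SE). Unadjusted p was under 0.05 for 309 genes, 143 higher and 166 lower. That count was 220 without NP13 replicate 1 and 599 without NP13 replicate 4. DESeq2 also called 0 genes. The interval lay within 2-fold for 90.6% of the 8526 more abundant genes and within 1.5-fold for 66.7%.

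In non-pregnant mares, day 13 was compared with day 11. Without a block for the corpus luteum, edgeR called 0 genes, with 415 genes at an unadjusted p under 0.05. The 415 became 268 without NP11 replicate 1 and 646 without NP11 replicate 2. With each corpus luteum as its own block, which compares the days within a gland, 4 genes rose and 0 fell. This effect rests on the 3 glands labelled non-pregnant on both days. ENSECAG00000017274, chosen after its values were seen, had the smallest adjusted p of these, 0.0191 in edgeR with the block. Its abundance was 43.1 ± 48.8 CPM (SD, n = 4) in NP13 and 2.89 ± 1.65 CPM (SD, n = 4) in NP11. NP13 replicate 1, from the first corpus luteum of Kate, held 2.46 CPM, and the other NP13 libraries held 13.4, 45.4 and 111 CPM. In the unblocked fit, ENSECAG00000035510 was at 2.25 ± 2.69 CPM (SD, n = 4) against 0.151 ± 0.0608 CPM (SD, n = 4), and ENSECAG00000017827 at 8.44 ± 2.47 CPM (SD, n = 4) against 15.8 ± 4.49 CPM (SD, n = 4), neither past the threshold. The log2 fold change of ENSECAG00000035510 was 3.85, and 2.53 without NP13 replicate 3. DESeq2 called 7 genes, all higher at day 13, and edgeR with the mare in place of the corpus luteum as a fixed block called 0.

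In pregnant mares the day comparison had 2 libraries at day 13 and 4 at day 11. The unblocked edgeR fit called 0 genes, with 345 at an unadjusted p under 0.05, of which 242 were higher and 103 lower. With the corpus luteum as a block 15 genes rose and 0 fell in the 2 glands sampled on both days, those of Emma and Cornelia, and the 4 genes called in non-pregnant mares were among them. Both day effects came from 1 fit with a shared estimate of the spread per gene, and the mare Emma is in both. The overlap is therefore not an independent replication. ENSECAG00000017274 again had the smallest adjusted p, 0.01 in edgeR with the block. Within these glands it went from 0.999 to 89.2 CPM in Emma and from 0.472 to 64.6 CPM in Cornelia. ENSECAG00000006694 was at 21.6 ± 8.64 CPM (SD, n = 2) against 1.14 ± 0.848 CPM (SD, n = 4), with an adjusted p of 0.24 in edgeR without the block and 0.0408 with it. Over all alternatives its adjusted p ran from 3.31e-05 to 1. ENSECAG00000012118, the gene with the smallest p among those lower at day 13, was at 7.59 ± 0.0792 CPM (SD, n = 2) against 11.2 ± 1.13 CPM (SD, n = 4). DESeq2 called 11 genes, all higher at day 13, and edgeR with the mare as a fixed block called 0. Without P11 replicate 3 the unblocked edgeR fit called 1 gene, and without both libraries of the first corpus luteum of Kate it called 2. In the blocked fit the first corpus luteum of Kate carries no weight on either day effect, because its status label changes between the days. The glands of Gisela and Roanie, sampled at day 11 alone, carry none either.

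**Figure D1:**
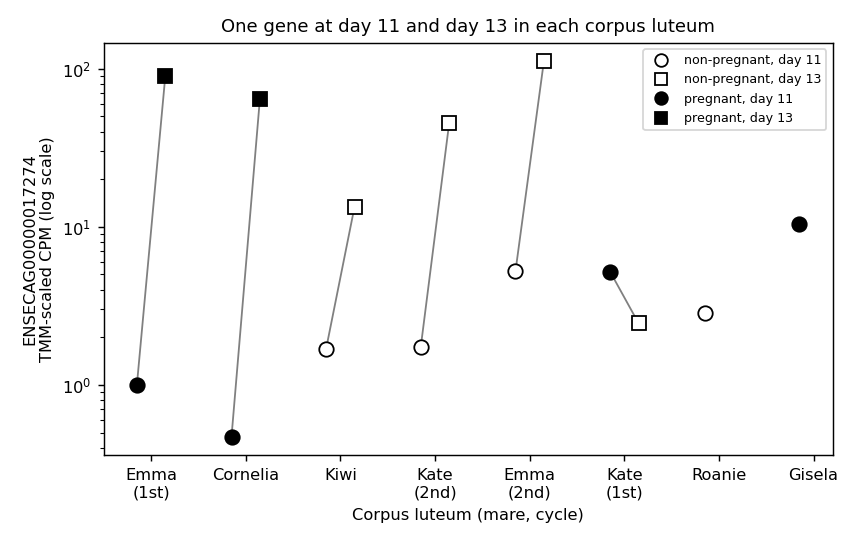
TMM-scaled CPM of ENSECAG00000017274 on a log axis, 1 point per library, with a line joining the day 11 and day 13 biopsies of a corpus luteum; filled symbols are pregnant and open symbols non-pregnant. The values at day 13 were above those at day 11 in 5 of the 6 corpora lutea sampled on both days, and the first corpus luteum of Kate went from 5.20 to 2.46 CPM.

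Averaged over both days, pregnant and non-pregnant libraries differed in 0 genes by edgeR, with 656 genes at an unadjusted p under 0.05 and 5 called by DESeq2. The 656 became 504 without NP11 replicate 3 and 1053 without P11 replicate 2. Chance would give about 772 if all libraries were independent, which they are not. The difference between the day effects of pregnant and non-pregnant mares was past the threshold for 0 genes in edgeR and 0 in DESeq2, with 257 at an unadjusted p under 0.05 in edgeR. These 257 became 136 without NP13 replicate 1, 405 without P11 replicate 1 and 102 without the first corpus luteum of Kate. With the corpus luteum as a block, added after the data were seen, edgeR also called 0 genes for this difference, with 244 at an unadjusted p under 0.05. The genes called under the block in pregnant mares alone were not shown to respond differently in non-pregnant mares. All 15 genes called under the block in pregnant mares had a log2 fold change over 1 in non-pregnant mares. Both effects come from the same fit, with Emma in both. A test of any difference among the 4 groups called 0 genes in edgeR, with 427 at an unadjusted p under 0.05, and 50 in DESeq2. It called 2 genes in edgeR without NP13 replicate 1 and 1 without P11 replicate 3.

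The stated purpose was to find genes with stable expression across status and day. Among the 8526 genes with a mean of at least 10 CPM, the SD of log2 CPM over the 14 libraries had a median of 0.191, with 5% of genes under 0.0996 and 5% over 0.529. There were 435 genes with an SD up to 0.1 and 70 with an SD over 1. ENSECAG00000009007 had the lowest SD, 0.0437, at 27.2 ± 0.828 CPM (SD, n = 14) and with values from 25.7 to 28.6 CPM. ENSECAG00000013216 followed with an SD of 0.0454 at 68.9 ± 2.14 CPM (SD, n = 14), then ENSECAG00000014617 with 0.0469 at 320 ± 10.4 CPM (SD, n = 14) and ENSECAG00000024994 with 0.0534 at 68.4 ± 2.52 CPM (SD, n = 14). These genes were picked as the lowest of 8526 SDs in the same 14 libraries, so their values may be low in part by chance. The share of counting noise in them was not estimated. The order depended on the processing: once mare means were removed these genes ranked 47, 2, 15 and 20, and 26 of the 100 most stable genes stayed among the 100. With no scaling beyond the library total 32 stayed. The confidence intervals of all 4 comparisons between groups lay within 1.5-fold for 5192 genes, or 60.9%, by a criterion chosen after the data were seen. Without P13 replicate 1 that number was 3011, and without P13 replicate 2 it was 3061.

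**Figure D2:**
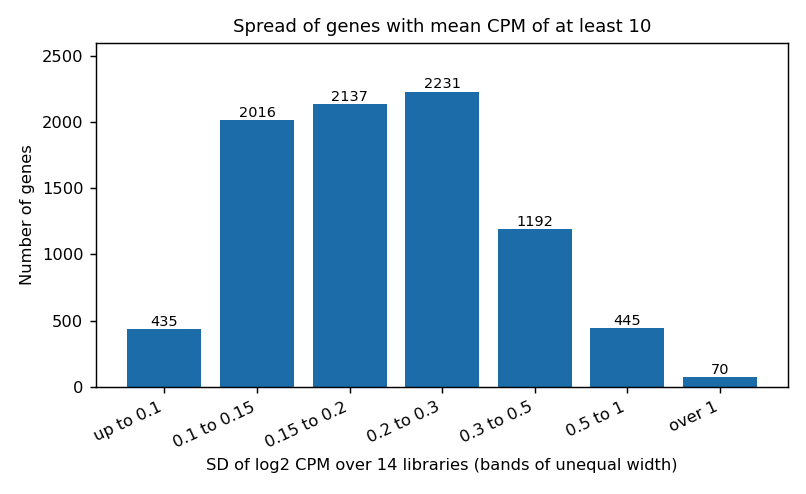
Number of genes, on the vertical axis, in each band of the SD of log2 CPM over the 14 libraries, for genes with a mean of at least 10 CPM; the bands differ in width. The band from 0.2 to 0.3 holds the most genes, 2231.

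Libraries of the same mare resembled each other more than libraries of different mares. Pairs were taken between groups, which left out 19 pairs within a group. The deviations from the group means correlated, across genes, with a mean r of 0.32 over 6 pairs from the same corpus luteum and 0.32 over 7 pairs from different corpora lutea of the same mare. Over 59 pairs of different mares the mean r was -0.07. Centring gives the 2 P13 libraries mirrored deviations, and without P13 the means were 0.37 over 4 pairs, 0.35 over 5 and -0.08 over 39. The difference between same-mare and other pairs was 0.39, with a p of 2e-04 in a one-sided permutation test that exchanged mares within groups 100000 times. The exchange also parted libraries of the same corpus luteum, so this p does not separate mare from gland. Genes are not independent replicates, and these correlations describe the libraries.

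**Figure D3:**
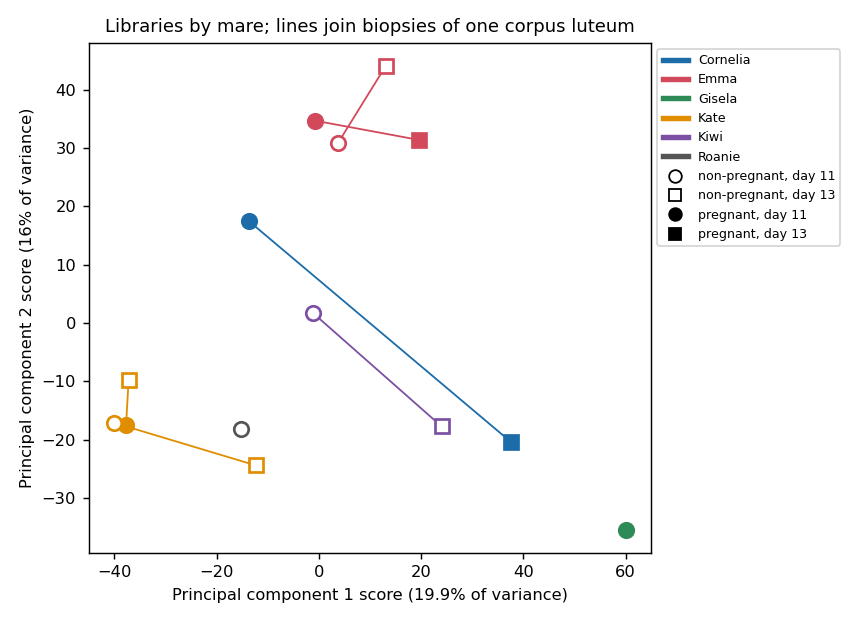
Scores of the 14 libraries on the first 2 principal components of log2 CPM, which hold 19.9% and 16% of the variance; colors are mares, and lines join the day 11 and day 13 biopsies of a corpus luteum. All 4 libraries of Emma lie above 30 on the second component, and P11 replicate 3, from Gisela, lies farthest right at 60 on the first.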

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

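The tests of biopsy month, of the single corpus luteum, of sequence differences, of depth, of tissue in P11 replicate 3, of an earlier biopsy, of pregnancy as a condition and of the 16 sign choices below were chosen after the results were seen. In each group of 4 libraries, single values were compared with the other 3 in 57 sets of values, and 4 stood apart from the rest. Chance alone would set apart about 1 in 20. ENSECAG00000023115 was at 10.15 CPM in NP11 replicate 2 against 9.508 to 9.586 in the others. ENSECAG00000013216 was at 71.35 CPM in NP11 replicate 3 against 67.77 to 68.21. ENSECAG00000035510 was at 6.286 CPM in NP13 replicate 3 against 0.8057 to 0.9962. ENSECAG00000006694 was at 2.41 CPM in P11 replicate 2 against 0.6659 to 0.7866.

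The counts of genes at an unadjusted p under 0.05 were no larger than other splits of the same libraries give. For pregnancy at day 11, 25 of 35 splits gave at least the real 638 genes, and the highest other split gave 2324. For day in non-pregnant mares, 25 of 35 splits gave at least the real 415, with a highest of 2081. For pregnancy averaged over days, 52 of 100 splits gave at least the real 656, with a highest of 2495. Chance was not excluded for any of these. The highest splits at day 11 and in non-pregnant mares parted 0 pairs of libraries from the same mare, and the real splits parted 2 and 4, which points to mares as a structure of the samples. Among the 12 splits that parted as many same-mare pairs as the real one, 6 gave as many genes at day 11, with a highest of 913, and 5 in non-pregnant mares, with a highest of 678. For pregnancy averaged over days, 19 of 32 such splits gave as many, with a highest of 1608.

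With group in the model, 1416 genes differed between mares in edgeR. Of 60 assignments of mare names to libraries, 1, the real one, gave as many, and the highest other gave 26. The assignments also parted libraries of the same corpus luteum. Chance was therefore excluded for a clustering of libraries by mare or gland, but not for mares apart from their glands. The number of genes called was 525 without NP11 replicate 4, 540 without P11 replicate 2, 561 without NP11 replicate 3, 693 without NP13 replicate 4, 730 without P11 replicate 1, 814 without NP13 replicate 2, 836 without NP11 replicate 2 and 930 without NP13 replicate 1. Biopsy month as the cause was argued against by Emma, whose 4 pairs of libraries from different months had a mean r 0.36 above that of different mares in the same month (0.4 without P13, over 2 pairs). The state of a single corpus luteum stays open: of 200 genes that differed most between the first corpora lutea of Emma and Kate, 83.5% kept their direction in the second, against 70.1% of all genes tested and short of the 90% set as a bound, while pairs from different corpora lutea of the same mare had a mean r of 0.32. Differences in sequence or copy number against the reference genome may also contribute and cannot be told apart from regulation, since 8 genes were under 0.1 CPM in all libraries of 1 mare and at 10 CPM or more in all of another.

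Genes higher at day 13 within corpora lutea were looked for in a fit pooled over status, with the corpus luteum as a block. That fit called 1 gene, which was higher at day 13. It called 0 when any 1 of the 5 glands other than the first of Kate was left out. With a minimum mean of 1 CPM the smallest adjusted p was 0.254 in edgeR, so no gene passed. At an unadjusted p under 0.05 there were 1011 genes, 615 higher and 396 lower at day 13. Of 32 choices of sign for the 6 corpora lutea, 10 gave as many, with a highest of 1476. Chance was therefore not excluded for that count. It takes both directions together and so does not test a rise alone. The 6 corpora lutea come from 4 mares and are not independent. Without the first corpus luteum of Kate, 62 genes were called, all higher, and 31 of them had a mean under 1 CPM. That gland was left out because its status label changes, but the pooled fit holds no status term. It is also the gland that lacks the rise: the 119 genes below had a median log2 change of 0 in it and 2.04 to 4.03 in the others. These genes were chosen in the pooled fit over the same 6 glands, so the values in the others are no independent evidence of a rise. With the days of the first corpus luteum of Kate exchanged, 46 genes were called, against 1 with the real days. The 62 calls thus depend on leaving out this gland. Of 16 sign choices without it, 1 gave as many and the highest other gave 1. These 16 choices, over glands that share mares, are too few for a share under 0.05. Depth was argued against as the cause, since the day 13 library was the deeper of the pair in 1 of 6 corpora lutea. Of 119 genes with p under 0.01 and a log2 fold change over 2, 74 were above all other day 11 libraries in P11 replicate 3, at a count of at least 10. The highest such number for any other day 11 library was 10. That contrast is in part set by the choice of genes, which favors low day 11 values in glands sampled on both days. P11 replicate 3, from Gisela, had no weight in that choice. Of the other day 11 libraries, only NP11 replicate 1, from Roanie, was as free of it. Many of the 119 genes were also raised in P11 replicate 3. Whether that library holds other tissue was not tested, since no marker genes could be named, so this explanation stays open. An effect of the earlier biopsy of the same corpus luteum cannot be told apart from day, since 0 day 13 libraries came from a gland not sampled before.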

How the results depend on the processing

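Unless stated, alternatives were fixed before the data were examined; the summary of the 100 most stable genes, the interval criterion, the interaction with the corpus luteum as a block, the mare test and the pooled day fit were added after. The count of genes past the threshold was 0 in edgeR for all 7 comparisons, and stayed 0 in all 7 with RLE size factors, with other low-count filters, with biopsy month as a covariate and with the mare as a fixed block. It also stayed 0 with the compared libraries alone, which was run for the 4 comparisons of 2 groups. DESeq2 called 2 genes for pregnancy at day 11, 7 and 11 for day in non-pregnant and pregnant mares, 5 for pregnancy averaged over days and 50 for any group difference. With the corpus luteum as a replicate block, 4 and 15 genes were called for day in non-pregnant and pregnant mares. The mare as a random block in limma-voom, with a correlation of 0.37, called 1 gene for day in pregnant mares. Other blocked fits changed no call. Without the corpus luteum labelled with both statuses, 1 gene was called for day in non-pregnant mares, 2 for day in pregnant mares and 2 for any group difference. The cause of these changes was not tested. Leaving out each library gave 0 to 1 genes for day in pregnant mares (1 without P11 replicate 3) and 0 to 2 for any group difference (2 without NP13 replicate 1, 1 without P11 replicate 3), and 0 elsewhere.

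The median SD of 0.191 became 0.235 with a minimum of 1 CPM, which adds less abundant genes, and 0.145 after removing mare means (a replicate block). It ran from 0.185 to 0.193 when each library was left out. Of the 100 most stable genes, 32 stayed among the 100 with no scaling beyond the library total and 26 after removing mare means, and 71 to 85 when a library was left out. The number of genes with all intervals within 1.5-fold ran from 3011 to 5164 when a library was left out, lowest without P13 replicate 1. Genes that differ between mares numbered 525 to 1708 when a library was left out, lowest without NP11 replicate 4. geNorm M, and all alternatives for the gene list tests, were not run because the identifiers matched no symbols.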

Other observations

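The test below was chosen after the pattern was seen. In each of the pregnant corpora lutea sampled on both days, 110 genes were at least 4-fold higher at day 13. The hypothesis that this difference belongs to pregnant mares only was argued against, since the median log2 change of these genes was over 1 in 3 of 3 corpora lutea labelled non-pregnant on both days. The second corpus luteum of Emma shares its mare with a gland in which the genes were chosen, and Kiwi and Kate gave none of those glands. The median was 1.85 in Kiwi, 3.31 in the second corpus luteum of Kate and 2.18 in the second of Emma, where the highest median of 10000 random lists matched on mean expression was 0.66, 0.53 and 0.33. In the first corpus luteum of Kate the median was -0.66, with 0% of the random medians below it. The random lists were matched on mean expression alone, not on genes that change together. They therefore give no chance range for such genes, and the result rests on the 3 glands. In a separate list, the 119 genes higher at day 13 in the pooled fit, with p under 0.01 and a log2 fold change over 2, 83 had a mean under 1 CPM. There were 2 genes past the same limits in the other direction. The sign of the first principal component was set so that day 13 libraries scored higher in total. Only the agreement between glands in the direction of change is therefore a result. The score was higher at day 13 in 6 of 6 corpora lutea, by 0.5 in the first of Kate and by 9.4 to 51.3 in the others. These 6 come from 4 mares and are not independent, so no test is given.

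Some genes were close to on or off by mare. ENSECAG00000028173 was at 702 to 1240 CPM in the 4 libraries of Kate, 996 to 1180 in the 2 of Cornelia and 1200 in the 1 of Roanie. It was at 6.42 to 11.5 CPM in the 4 libraries of Emma, 3.77 to 5.5 in the 2 of Kiwi and 6.14 in the 1 of Gisela. Its adjusted p for a difference between mares was 4.64e-07 in edgeR. In genes with a mean of at least 10 CPM the median adjusted share of variance by mare was 38%, against -12% by group. The adjustment for the number of classes allows values under 0. A median under 0 does not by itself mean less than chance gives. Libraries of the same corpus luteum share a mare, so the share by mare holds differences between glands too.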
